A study of Homo sapiens with 6 samples.

How the data were processed

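RNA sequencing data came from cultures of the MCF7 breast cancer cell line, established in vitro from xenografts, in 3 groups of 2 samples: vehicle control (TC), tamoxifen with a dormancy-like state (TD) and tamoxifen with relapse (TR). Per the labels' protocols, cells were collected in TRIzol, total RNA was taken and BGI made the libraries. Nothing in the labels says whether the samples of a group were separate cultures. The submitters' processing notes name HISAT2 2.0.4, DESeq2 1.4.5 and the build GRCh38.p13, with no role or order. The quantifier, the gene annotation, the library's strandedness and the filter that chose the genes are not given in the sources used here.

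Per the file headers, the authors deposited TPM, FPKM and estimated count columns for TC, TD and TR, the estimated counts being reads assigned to genes and TPM and FPKM being scaled for gene length and depth. Each group has 1 column per unit, and it is not stated whether a column is a single library, pooled reads or a mean of 2. The deposited TPM and FPKM values differ by 1 constant factor per column (1.39 in TC, 1.47 in TD and 1.31 in TR), and 86.7% to 87.2% of the deposited estimated read counts were whole to 2 decimals. The larger of a gene's FPKM folds in TD and TR against TC was at least 2 for all 2236 genes, so the authors' deposited FPKM table had been selected for difference. In FPKM, 466 genes were under 2-fold in TD against TC and 1285 in TR against TC. The listed TPM summed to 78349 in TC, 56389 in TD and 74001 in TR, out of all TPM of the library, so the totals of the table are not library depths. Relative depth was estimated from 140 genes with over 20 FPKM and over 500 reads in every column, as 1.03 for TD and 1.02 for TR relative to TC. TPM and FPKM log2 ratios differ by a constant shift of 0.08 for TD versus TC, -0.09 for TR versus TC and -0.17 for TR versus TD.

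The tests planned before the data were examined (edgeR or limma over 6 samples, camera for gene lists, adjusted p under 0.05) need a value per sample and could not be run. In their place, log2(TPM + 1) differences were taken between columns for 2031 genes with at least 1 TPM in at least 1 column, and a gene was counted where the difference was at least 1, that is 2-fold. A pseudocount of 1 understates the difference of low genes, and ratios in the text are of TPM without it. Each ratio has an exact Clopper-Pearson 95% interval of the ratio of the rounded read counts, multiplied so that it is centred on the TPM ratio. Relative depth enters the floors, the read count alternative and the count of interferon genes with an interval above 1. The sources mention no molecular identifiers, so intervals and floors cover counting error only. Where a gene had 0 reads in a column, the fold is a lower bound against 3 reads in that column. The smallest number of reads a gene had in its highest column was 11.

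Before the data were examined, 38 gene lists were fixed. They covered oestrogen receptor, luminal, basal, stem and dormancy, mesenchymal, cell cycle, p53, interferon, antigen presentation, inflammatory, stress, metabolic, signalling, apoptosis, DNA repair, histone, chromatin, steroid receptor, ribosomal, keratinisation and mucin genes, and markers of stroma, leukocytes, endothelium and adipocytes as cells the xenograft host could have left. Of these, 22 had at least 5 listed members. A list's median log2 ratio was placed among 10000 random lists of the same size drawn from the listed genes and matched on mean level in 10 bins, which describes these columns and tests no condition. The planned rule for named genes asked for an adjusted p and separation of replicates, and those parts could not be applied. What remained of it named, per comparison, the 10 largest differences in each direction with at least 5 TPM in the higher column and no clone symbols, the 4 list members with the largest differences where at least 3 were past 2-fold (all such members otherwise), and 9 genes by name.

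Positions and the GC content of the longest transcript came from GENCODE 29 on GRCh38, to which 2201 genes (98.4%) were matched, 47 of them by Ensembl gene identifier alone. Genes whose estimated counts were not whole are reported as uncertain, and the cause of the fractions was not tested. The interval and the 2-fold rule were tested on simulated data, with Poisson counts drawn around the mean of the 3 columns (2236 genes, 200 of them changed): 95.2% of intervals held the true ratio, 98.0% of genes with a true ratio of 4 and 20.5% with a true ratio of 2 passed 2-fold, and 0.058% of unchanged genes did. The percentile was tested on values drawn from a normal distribution with an SD of 1.5 on the log2 scale. Of 500 unshifted lists of 12 genes 5.2% lay beyond the central 95%, against 97% of lists shifted by 2 on the log2 scale. That shift is larger than most list medians reported below. The simulated values held no related list members and no selection for difference, so these shares need not hold for the lists reported. The list part was first run with 100 lists on 1 set of values and was then given fresh values for each list. The histone symbols were matched through gene identifiers after first results had been seen.

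Alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 TPM and quantile normalization of the listed genes. Added after seeing the data were FPKM in place of TPM, read counts over relative depth, centring of the log2 values within 10 bins of GC content, and random lists matched on GC content in 5 bins as well as level in 5 bins. The read count alternative first used a pseudocount of 1 read and was then given a pseudocount equal to 1 TPM. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.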

Results

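RNA was sequenced from cultures of MCF7, an established oestrogen receptor-positive breast cancer cell line, that had been grown as xenografts and then brought back into culture. The labels describe 3 groups of 2 samples each: vehicle-treated controls (TC), a dormancy-like state under tamoxifen (TD) and a relapsed state under tamoxifen (TR). Tamoxifen is an oestrogen receptor antagonist used against breast cancer. The table analysed here holds 1 column per group rather than 1 per sample, so no difference below has a replicate check, no test between groups was run, and "higher" and "lower" describe these 3 columns alone. It lists 2236 genes, each at least 2-fold different in FPKM from the control column in TD, in TR or in both, so the counts of differing genes and the gene lists are not independent evidence of change, and unlisted genes were not analysed here. The listed genes held 1234628 estimated reads in TC, 1469657 in TD and 1166650 in TR, with a median of 151, 138 and 132 reads per gene. They made up 7.83% of the total TPM, a length-scaled share of transcripts, in TC, 5.64% in TD and 7.40% in TR. Ratios are given with the 95% exact interval of the read counts, which covers counting error only and not the spread between cultures. In counts of list members, higher and lower mean at least 2-fold on the log2(TPM + 1) scale.

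The first comparison asked how the dormancy-like cultures differed from the vehicle controls. Genes of the interferon response were lower in TD. Of the 37 symbols fixed for this list 30 were listed. Of these, 20 were at least 2-fold lower on the log2(TPM + 1) scale and none was at least 2-fold higher. The interferon-induced gene IFI27 (GRCh38 chromosome 14, 94104836 to 94116698) stood at 89.17 TPM in TC and 1.77 TPM in TD, 50.4-fold lower (95% interval 24.2 to 126). IFI6 was at 551.49 TPM in TC and 29.35 TPM in TD, and ISG15, a ubiquitin-like protein induced by interferon, was at 553.01 and 80.16 TPM. OAS1, a sensor of double-stranded RNA, stood at 21.82 TPM in TC and 2.39 TPM in TD. The list's median log2 ratio was -1.31, below each of 10000 random lists of listed genes matched on level (percentile 0).

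For the oxidative stress and NRF2 list, 7 of the 26 fixed genes were listed, with 5 at least 2-fold higher in TD and 1 lower (median 1.90, percentile 99.9). The 5 higher members were HMOX1, SLC7A11, AKR1C1, AKR1C2 and AKR1C3. Fixed genes that were not listed included NQO1, GCLC, GCLM, TXNRD1, SRXN1 and G6PD. The aldo-keto reductases AKR1C1, AKR1C2 and AKR1C3, neighbouring genes for enzymes that reduce steroids and reactive carbonyls, stood out (GRCh38 chromosome 10, from 4963253 to 5107686). AKR1C1 stood at 0.60 TPM in TC and 67.16 TPM in TD, 112-fold higher (95% interval 77.3 to 169). AKR1C3 was at 12.61 and 364.53 TPM, 28.9-fold higher (95% interval 24.5 to 34.5), and AKR1C2 was at 15.9 and 287.97 TPM. These related genes had estimated counts that were not whole, so their separate levels are uncertain. They were counted as separate genes in the list's median and percentile, although the random lists take genes as independent. HMOX1, the haem oxygenase that is a marker of oxidative stress, stood at 6.83 TPM in TC and 28.17 TPM in TD. The member of this list that was lower was OSGIN1, at 31.55 TPM in TC and 10.07 TPM in TD.

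Of 6 listed members of the androgen and glucocorticoid receptor list, out of 18 fixed, 4 were at least 2-fold higher in TD and none was at least 2-fold lower (median 1.84, percentile 99.9). The other listed members were the receptors themselves, with AR at 3.77 TPM in TC and 1.57 TPM in TD, and NR3C1, whose counts were not whole and whose level is uncertain, at 9.41 and 4.96 TPM. TSC22D3, a glucocorticoid-induced leucine zipper protein, was at 45.19 TPM in TC and 424.77 TPM in TD, 9.40-fold higher (95% interval 8.79 to 10.1). SGK1 stood at 3.19 and 30.98 TPM, and TMPRSS2 at 10.02 and 64.58 TPM. Of 6 listed replication-dependent histones, out of 26 fixed symbols, 5 were higher and 1 was lower (median 1.64, percentile 99.7). H2AC6 stood at 100.68 TPM in TC and 359.31 TPM in TD, while H2AC20 was at 62.5 and 20.54 TPM. H2AC19, a histone gene outside the fixed list, was lower as well, at 151.15 TPM in TC and 0 TPM in TD and TR, and is uncertain since its counts were not whole and it has a near-identical copy.

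Listed genes of S phase and DNA replication, 12 of 32 fixed, were lower in TD, where 8 were at least 2-fold lower and none was higher. Thymidine kinase TK1 was at 140.5 TPM in TC and 51.92 TPM in TD, 2.71-fold lower (95% interval 2.48 to 2.95). GINS4, a part of the replicative helicase, stood at 5.75 and 1.48 TPM, and the chromatin assembly factor CHAF1B at 19.61 and 6.94 TPM. This list's median of -1.06 lay within the central 95% of random lists (percentile 7.08). Of the 30 genes fixed for G2 and mitosis only PLK1 was listed, at 70.46 TPM in TC, 78.45 TPM in TD and 133.91 TPM in TR.

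Oestrogen receptor targets went both ways, with 4 of 15 listed members higher in TD and 4 lower (median -0.06, percentile 76.2). TFF1, a secreted peptide encoded by a classical oestrogen-regulated gene (chromosome 21, 42362282 to 42366594), was the most abundant of them. It stood at 18797 TPM in TC and 2495 TPM in TD, 7.53-fold lower (95% interval 7.34 to 7.73). The chemokine CXCL12 was at 39.22 TPM in TC and 287.37 TPM in TD, and the kinase receptor RET at 48.89 and 15.86 TPM. Among 5 listed p53 targets 3 were higher and 2 were lower in TD (median 1.28, percentile 96.9). The cell cycle inhibitor CDKN1A stood at 153.65 TPM in TC and 374.5 TPM in TD, 2.44-fold higher (95% interval 2.34 to 2.54). Of the 9 genes chosen by name before the data were examined, TFF1 and CDKN1A were listed, and ESR1, PGR, GREB1, MKI67, CCND1, ERBB2 and NR2F1 were not.

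Over 2031 genes with at least 1 TPM in a column, 1019 differed at least 2-fold between TD and TC, 516 of them higher in TD and 503 lower. The balance depended on the scaling: FPKM gave 414 higher and 513 lower, read counts over depth 457 and 576, a pseudocount of 0.1 670 and 764, and GC centring 429 and 285. The calcium-binding protein S100A4 was at 3.02 TPM in TC and 88.25 TPM in TD, from 10 reads in TC. CLEC7A, a pattern recognition receptor, had 0 reads in TC and 18.44 TPM in TD, at least 96.2-fold higher against a floor of 3 reads. The insulin-like growth factor binding protein IGFBP5 stood at 66.72 TPM in TC and 356.18 TPM in TD, and RARRES2, which encodes the secreted adipokine chemerin, at 3.10 and 64.38 TPM. UGT1A6, a glucuronidating enzyme, was at 2.8 and 58.64 TPM, and IGSF1 was at 3.64 and 65.37 TPM. CAB39L was at 4.93 and 81.32 TPM, and METTL7A at 4.71 and 75.81 TPM. CLEC7A, UGT1A6, CAB39L and KRT81 had counts that were not whole, so their levels are uncertain. Among the lower genes the hair keratin KRT81 was at 280.12 TPM in TC and 4.58 TPM in TD, the smooth muscle actin ACTG2 at 144.11 and 3.92 TPM, and the metallothionein MT1F at 75.25 and 7.3 TPM. Redrawing the reads of 3 unchanged columns gave a mean of 0.75 and at most 3 such genes in 100 draws. The draws covered the listed genes alone, which had been selected for difference from a larger set. They therefore do not give the number that counting noise could have brought into the table. They do not measure the variation between cultures either.

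Across the listed genes the TD over TC ratio was lower at higher GC content (rank correlation -0.364 across 2003 genes, which are not independent replicates). Of the genes in the lowest of 10 bins of GC content 69.2% were higher in TD, against 12.4% in the highest bin. The same correlation for TR over TC was 0.07. Transcript length went with both ratios across genes, with a rank correlation of 0.214 for TD over TC and -0.205 for TR over TC. When random lists were also matched on GC content, an alternative added after seeing the data, the interferon, oxidative stress, histone and steroid receptor lists lay at percentiles 0, 99.7, 98.9 and 99.8 in TD against TC. Markers of other cell types were few: the macrophage marker CD68 was at 6.36 TPM in TC, 1.35 TPM in TD and 6.09 TPM in TR. Smooth muscle actin ACTA2 was at 15.89, 3.04 and 64.43 TPM, the collagen gene COL6A2 at 15.63, 7.16 and 11.61 TPM, and the adipocyte gene PLIN1 at 0.16, 1.9 and 0.12 TPM.

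**Figure D1:**
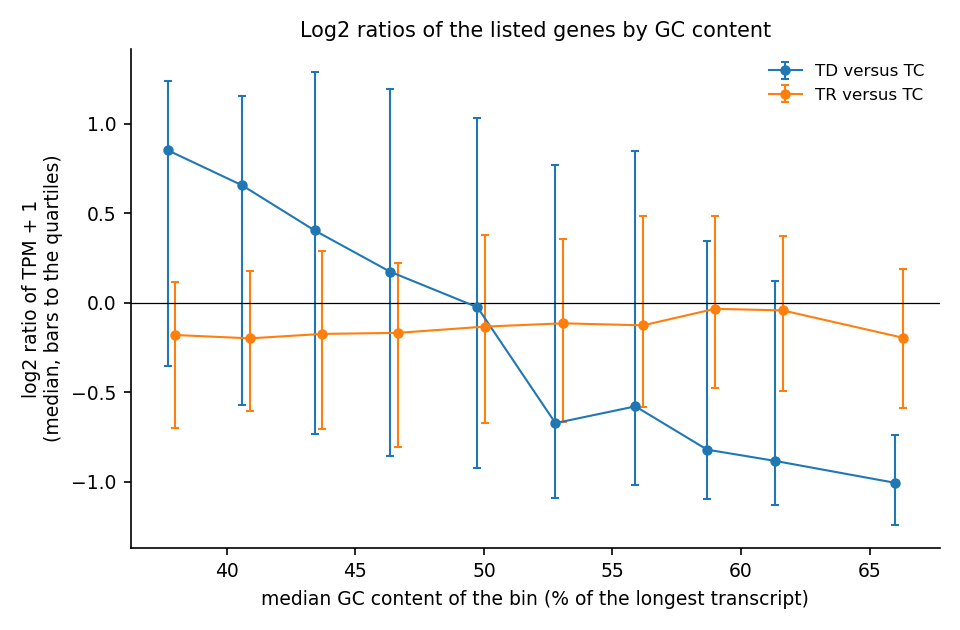
Median log2 ratio of TPM + 1 in 10 bins of the listed genes by GC content of the longest transcript, for TD over TC (blue) and TR over TC (orange); bars reach the quartiles and the series are offset slightly sideways. The TD over TC median goes from 0.85 in the bin of lowest GC content to -1.01 in the bin of highest, and the TR over TC medians lie between -0.20 and -0.03.

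The next comparison set the relapsed cultures against the vehicle controls. Interferon response genes were higher in TR, with 20 of 30 listed members at least 2-fold higher and none at least 2-fold lower (median 1.42, percentile 100). IFIT1, an RNA-binding antiviral protein, stood at 4.84 TPM in TC and 40.76 TPM in TR, OAS2 at 6.48 and 49.69 TPM, and IFI27 at 89.17 and 412.03 TPM. OAS2 was 7.67-fold higher (95% interval 6.75 to 8.73). Of 8 listed antigen presentation genes, out of 23 fixed, 4 were higher and 1 was lower in TR (median 0.83, percentile 99.9). The peptide transporter gene TAP2 was at 10.62 TPM in TC and 26.09 TPM in TR, and HLA-DRB1 was the lower member at 62.19 and 23.73 TPM, a level that is uncertain as its counts were not whole.

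Immediate early genes were also mostly higher in TR, while keratinisation genes went both ways. Of 11 listed AP-1 and immediate early genes, out of 30 fixed symbols, 6 were at least 2-fold higher and none was at least 2-fold lower (median 1.02, percentile 99.96). FOS was at 16.57 TPM in TC and 42.91 TPM in TR, MYC at 25.11 and 63.05 TPM, and the phosphatase DUSP5 at 0.63 and 5.17 TPM. In the stratified epithelium and keratinisation list, 11 of 20 fixed genes were listed, 6 of them higher and 3 lower (median 1.16, percentile 99.99). Counting differences of any size, 6 were higher and 5 lower. The median is thus the value of 1 gene, KRT16, the smallest of the 6 rises. S100A7, an antimicrobial protein of keratinocytes, stood at 1.93 TPM in TC and 112.11 TPM in TR, 58.1-fold higher (95% interval 22.4 to 215), from 4 reads in TC. S100A8 stood at 1.64 TPM in TC and 81.25 TPM in TR, from 3 reads in TC (ratio 49.5, 95% interval 16.6 to 243). S100A9, its binding partner in calprotectin, was at 4.47 TPM in TC and 45.87 TPM in TR.

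The fixed list of calcium-binding and mucin genes was lower in TR, with 8 of 11 listed members at least 2-fold lower and none at least 2-fold higher (median -1.27, percentile 0.00). The higher S100A7, S100A8 and S100A9 stood in the keratinisation list instead. The lower members included TFF1 and TFF3, which are also on the oestrogen receptor target list. The membrane mucin MUC1 (chromosome 1, 155185824 to 155192916) stood at 39.27 TPM in TC and 3.66 TPM in TR, 10.7-fold lower (95% interval 8.63 to 13.5). S100A14 was at 362.38 TPM in TC and 77.37 TPM in TR, and S100A16 at 518.77 and 117.53 TPM. Of 10 listed receptor tyrosine kinases and ligands, out of 30 fixed, 5 were lower and 1 was higher (median -0.90, percentile 0.33). The kinase receptor ERBB4 was at 4.6 TPM in TC and 0.41 TPM in TR, and the binding protein IGFBP3 at 9.16 and 0.97 TPM. The ligand AREG was the higher member, at 46.44 and 101.45 TPM. Among oestrogen receptor targets 4 of 15 were higher and 5 were lower (median 0.10, percentile 90.7), with TFF1 at 7780 TPM in TR, 2.42-fold below TC (95% interval 2.38 to 2.45). CDKN1A stood at 289.56 TPM in TR. No listed S phase gene reached 2-fold between TR and TC (median 0.00, percentile 77.3).

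In all, 479 genes differed at least 2-fold between TR and TC, 202 higher in TR and 277 lower. Quantile normalization of the listed genes gave 253 higher and 219 lower, and centring within 10 bins of GC content gave 288 higher and 150 lower, so the balance of the directions depended on the scaling. The growth factor midkine, MDK (chromosome 11, 46380756 to 46383837), was at 5.83 TPM in TC and 279.06 TPM in TR, 47.9-fold higher (95% interval 35.2 to 66.9). The myosin light chain MYL9 was at 0.03 TPM in TC, from 1 read, and 25.99 TPM in TR (ratio 866, 95% interval 155 to 34258). CT83 had 0 reads in TC and 21.43 TPM in TR, at least 22.1-fold higher against the floor of 3 reads. FCGRT was at 0.66 and 26.66 TPM, the matrix Gla protein MGP at 9.44 and 119.25 TPM, and the neuropeptide NPW at 2.18 and 26.52 TPM. Among the lower genes the pluripotency factor SOX2 (chromosome 3, 181711924 to 181714436) was at 24.94 TPM in TC and 0.51 TPM in TR, 48.9-fold lower (95% interval 29.4 to 87.9). TXNIP, an inhibitor of thioredoxin, was at 118.47 and 19.15 TPM, the ligand SHH at 7.4 and 0.55 TPM, PSCA at 21.37 and 2.84 TPM, and the glypican GPC6 at 8.27 and 0.65 TPM. BPIFB1 was at 5.68 TPM in TC and 0.11 TPM in TR, from 2 reads in TR, 51.6-fold lower (95% interval 13.9 to 432). SPANXA2, SULT1A4 and EIF3CL were also past the size rule, but their counts were not whole and are uncertain.

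**Figure D2:**
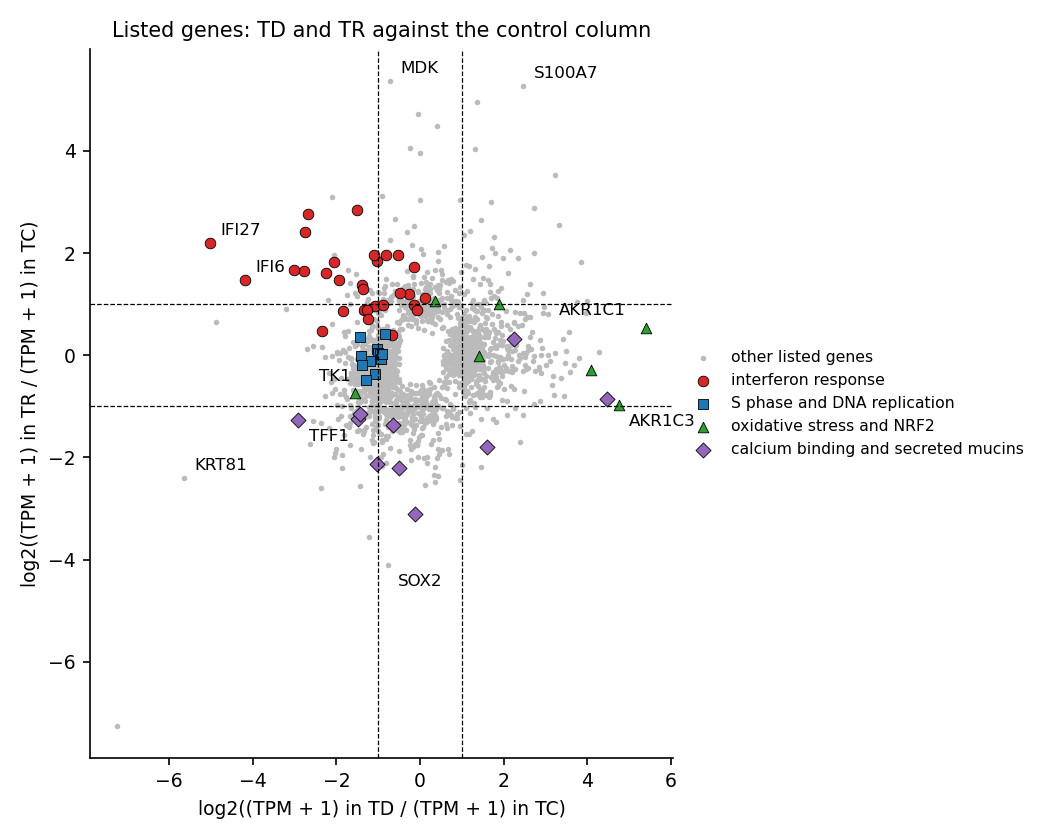
Each point is 1 of 2031 listed genes, with the log2 ratio of TPM + 1 in TD over TC on the horizontal axis and in TR over TC on the vertical axis. Dashed lines mark 2-fold. On this scale 701 genes were under 2-fold from TC in both columns, although the table had been selected for 2-fold differences in FPKM. Of 30 interferon genes (red) 29 lie at upper left and 1 just right of no difference in TD, with IFI27 at -5.02 and 2.20. S phase genes (blue) lie at left near the level of no difference in TR, and oxidative stress genes (green) and mucin genes (purple) elsewhere.

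Some genes stood apart from the controls in the same direction in both tamoxifen groups. Of the 2031 genes, 123 were at least 2-fold from TC in TD and TR alike, 49 higher and 74 lower. This number depended on the pseudocount, with 229 at 0.1 and 35 at 5. Independent lists of these sizes would share 51.3 higher and 68.6 lower genes, and unchanged columns sharing the TC reads gave a mean of 0.18. Because every listed gene had to differ in TD or in TR, neither value is a fair expectation for this table, and both comparisons use the same control column. MGP was among the shared higher genes, at 96.09 TPM in TD and 119.25 TPM in TR against 9.44 TPM in TC. The retinoic acid-binding protein CRABP2 was at 184.92 TPM in TC, 610.13 TPM in TD and 795.36 TPM in TR. TFF1 and TFF3 were shared lower genes, with TFF3 at 251.31 TPM in TC, 92.3 TPM in TD and 111.89 TPM in TR. KRT81 was also lower in both, at 52 TPM in TR.

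The last comparison set relapse against the dormancy-like state. Interferon genes differed most, with 29 of 30 listed members at least 2-fold higher in TR and none lower (median 2.72, percentile 100). IFI27 was 233-fold higher in TR than in TD (95% interval 113 to 580), from 7 reads in TD. OAS2 was 292-fold higher (95% interval 154 to 640), from 9 reads in TD, and IFI6 was 52.2-fold higher (95% interval 45.2 to 60.5). The antiviral membrane protein BST2 stood at 5.7 TPM in TD and 171.94 TPM in TR. Antigen presentation genes were higher in 5 of 8 cases (median 1.05, percentile 99.4). The immunoproteasome subunit PSMB9 was at 0.22 TPM in TD, from 2 reads, and 10.84 TPM in TR (ratio 49.3, 95% interval 13.3 to 412). AP-1 and immediate early genes had 6 of 11 members higher and 2 lower (median 1.05, percentile 99.6), with FOS at 12.17 TPM in TD and 42.91 TPM in TR. S phase genes were higher in TR than in TD in 7 of 12 cases and lower in none (median 1.07, percentile 98.2). Their log2 ratios for TR over TC lay between -0.48 and 0.41. The difference between TR and TD thus restates their lower TD values and is not a separate result. In TD against TC the list lay within the central 95%. TK1 was 2.66-fold higher (95% interval 2.45 to 2.90), and MCM2, a part of the replicative helicase, stood at 43.49 TPM in TD and 97.48 TPM in TR.

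**Figure D3:**
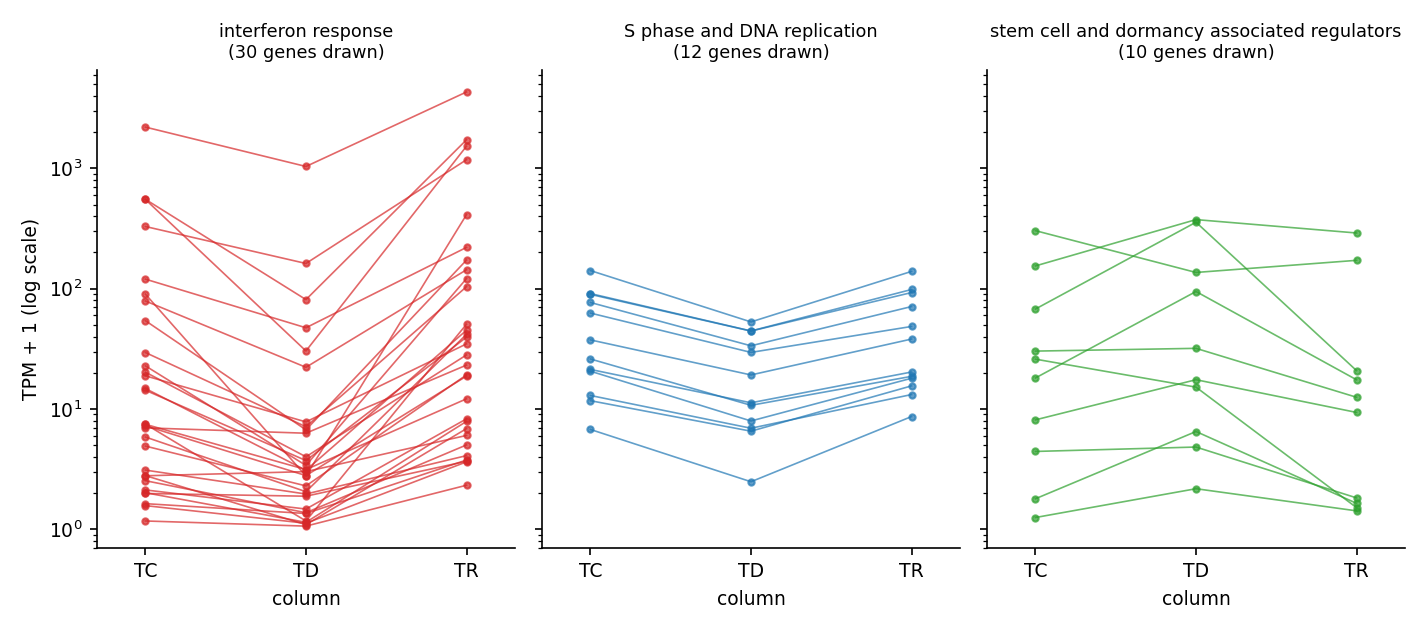
TPM + 1 on a log axis of the listed members of 3 gene lists in the TC, TD and TR columns, 1 line per gene and 1 value per column. Each of the 30 interferon genes is higher in TR than in TD, and the 12 S phase genes are lower in TD than in TC.

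Stem cell and dormancy associated regulators, listed for 10 of 29 fixed symbols, were mostly lower in TR than in TD. Of the 10, 6 were at least 2-fold lower and none was at least 2-fold higher (median -1.38, percentile 0.66). Against TC the list lay within the central 95% of random lists in both columns. In TD 5 members were higher than in TC and 1 was lower (median 0.95, percentile 96.3). In TR none was higher than in TC and 4 were lower (median -0.47, percentile 7.65). The hyaluronan receptor CD44 stood at 17.09 TPM in TC, 93.76 TPM in TD and 16.47 TPM in TR. IGFBP5 (chromosome 2, 216672105 to 216695525) was at 19.82 TPM in TR, 18.0-fold below TD (95% interval 17.1 to 18.9), and SOX2 was at 14.18 TPM in TD and 0.51 TPM in TR. Receptor tyrosine kinases and ligands were lower in 5 of 10 cases and higher in 1 (median -1.34, percentile 0.63), with the ephrin receptor EPHA2 at 64.23 TPM in TD and 6.04 TPM in TR. Of 6 members of the androgen and glucocorticoid receptor list 3 were lower in TR (median -1.50, percentile 2.01), TSC22D3 being at 25.9 TPM. Calcium-binding and mucin genes had 6 of 11 members lower and 1 higher (median -1.10, percentile 2.20). S100A6 stood at 325.1 TPM in TD and 29.87 TPM in TR. With a pseudocount of 0.1 the S phase, steroid receptor and mucin lists of this comparison lay within the central 95%, as did the mucin list with quantile normalization.

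Between TR and TD 994 genes differed at least 2-fold, 437 higher in TR and 557 lower. FPKM turned that balance, with 482 higher and 450 lower, as did read counts over depth, with 537 and 493. MDK was 87.8-fold higher in TR (95% interval 58.3 to 139), and ACTG2 was at 3.92 TPM in TD and 226.46 TPM in TR. AKR1C3 was 61.7-fold lower in TR (95% interval 48.9 to 79.0), at 5.91 TPM, and AKR1C1 and AKR1C2 were at 1.33 and 12.82 TPM. The transcriptional repressor TBX3 was at 29.47 TPM in TD and 1.03 TPM in TR, ZNF488 at 26.4 and 0.88 TPM, and C14orf132 at 151.38 and 7.09 TPM. The rank correlation of GC content with TR over TD was 0.376, and that of transcript length was -0.317, so shorter transcripts tended to be higher in TR than in TD.

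Most of what set TD apart from TC was not seen in TR. Of the 1019 genes at least 2-fold from TC in TD, 626 (61.4%) differed at least 2-fold in the opposite direction between TR and TD. Of these, 376 were higher in TD and 250 were lower in TD, and 570 were within 2-fold of TC in TR. Both comparisons use the TD column, so a deviation of that column alone would give the same pattern. Redrawn counting noise gave a mean of 0.19 and at most 2 such genes, in the listed genes alone and without allowance for how they were selected. AKR1C2, at 15.9 TPM in TC, 287.97 TPM in TD and 12.82 TPM in TR, was among them, as were CAB39L at 4.93, 81.32 and 4.71 TPM and TK1 at 140.5, 51.92 and 138.27 TPM. The growth differentiation factor GDF15 stood at 32.23, 140.05 and 36.69 TPM. The basal keratin KRT17 was at 380.82 TPM in TC, 57.67 TPM in TD and 414.21 TPM in TR.

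**Figure D4:**
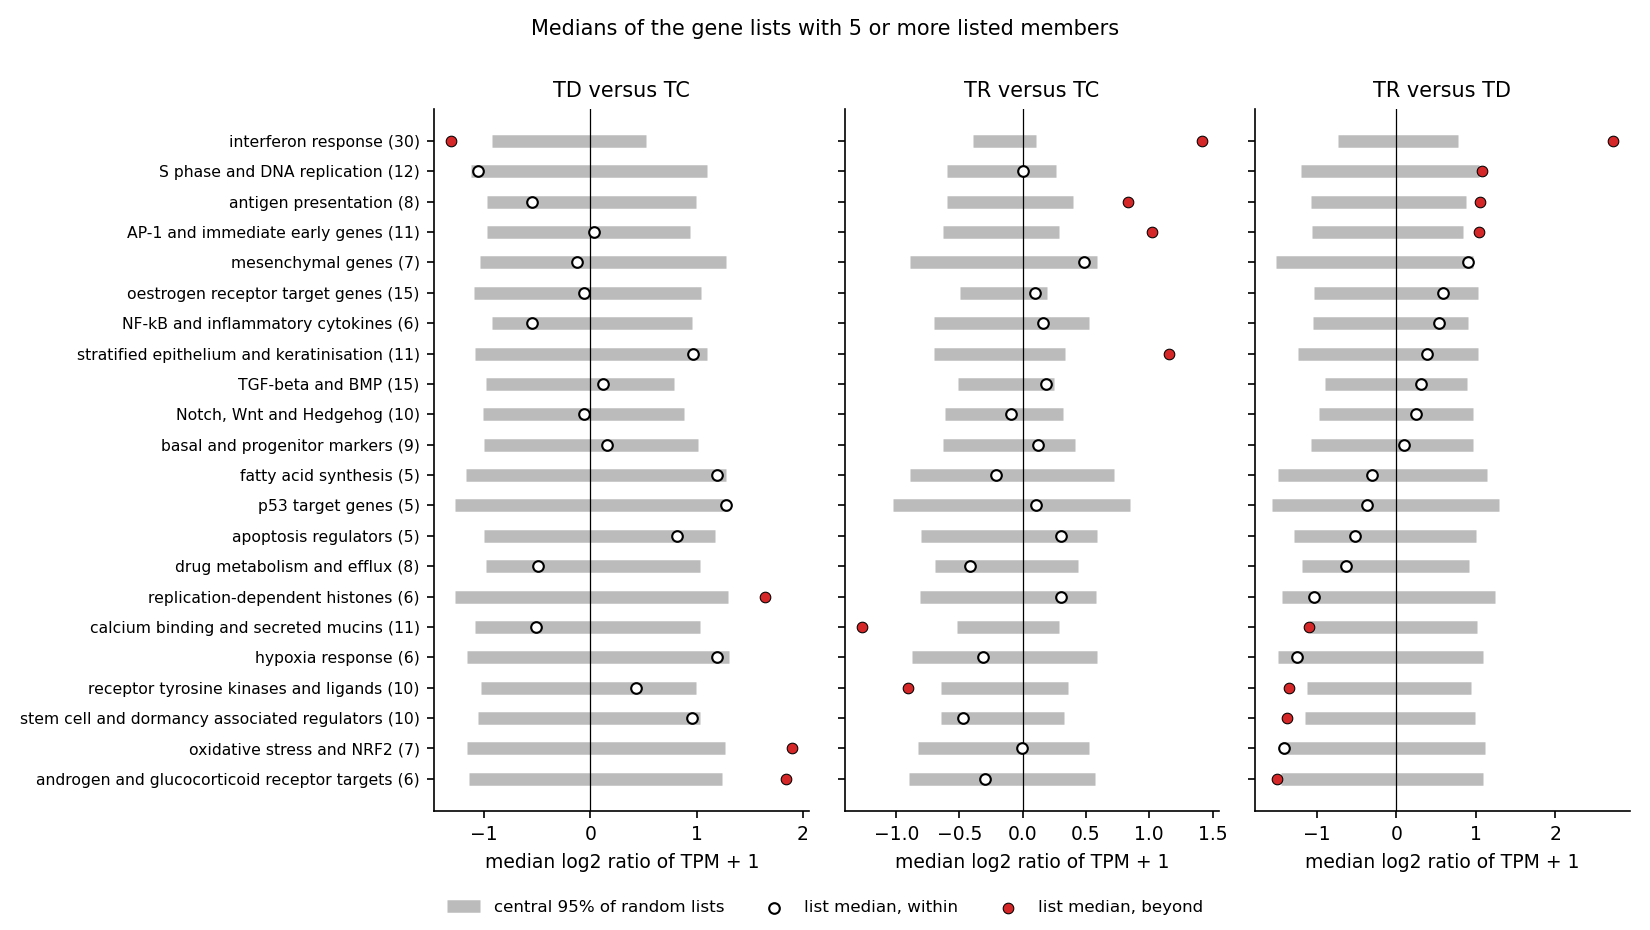
Median log2 ratio of TPM + 1 of the 22 gene lists with at least 5 listed members (number listed in parentheses) in the 3 comparisons; grey bars span the central 95% of 10000 random lists matched on level, and filled red points lie beyond it. Beyond it lie 4 lists for TD versus TC, 6 for TR versus TC and 8 for TR versus TD, with the interferon list beyond in each.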

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

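The tests on the interferon genes for GC content and read number were set before their results were seen, and the one for host leukocytes after. The interferon list stood on opposite sides of the control in the TD and TR columns, with a median log2 ratio of 2.72 for TR over TD. With 1 column per group this difference between the groups was not tested. GC-dependent yield of the TD library is argued against as the whole cause: among random lists matched on level and GC content the TR over TD median lay at percentile 100. Few reads are argued against too, since 30 of 30 listed members had a counting interval of TR over TD above 1. Selection of the members for a 2-fold difference from TC favours intervals away from 1, though it does not set their direction. Reads from host leukocytes or other host cells cannot be told apart from expression in the cultured cells, because only 1 of 14 leukocyte markers, CD68, was listed. Its log2 ratio was -0.0539 for TR over TC, and it stood at 6.36 TPM in TC, 1.35 TPM in TD and 6.09 TPM in TR. The stroma marker ACTA2 went with the interferon genes at 15.89, 3.04 and 64.43 TPM. The other listed stroma marker, COL6A2, was lower in TR than in TC, at 15.63, 7.16 and 11.61 TPM. The adipocyte marker PLIN1 went against the interferon genes in TD, with a log2 ratio of 1.32 for TD over TC. The state of the cultures, the handling of a single culture and the unknown pooling stay open as untested explanations.

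In single genes, 28 were at least 2-fold lower in TD than in TC and at least 2-fold higher in TR than in TC, and 14 of them were members of the interferon list. The opposite, higher in TD and lower in TR, held for 17 genes, among them IGFBP5 at 66.72 TPM in TC, 356.18 TPM in TD and 19.82 TPM in TR, STC2 at 70.52, 151.81 and 23.68 TPM and GSTM3, whose counts were not whole and whose level is uncertain, at 143.11, 340.39 and 50.78 TPM. Neither set was tested.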

How the results depend on the processing

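FPKM, read counts over depth, GC centring and GC-matched lists were chosen after seeing the data. No paired analysis was possible because the table has 1 column per group and carries no replicate number. For the same reason leaving out replicates, a fit of 4 samples, DESeq2, limma without a trend, an estimated correlation and other adjusted p thresholds were not run. With a pseudocount of 0.1, TR differed from TC in 752 genes and 229 were shared between TD and TR, against 479 and 123. With a pseudocount of 5, the counts were 446 for TD versus TC, 181 for TR versus TC, 483 for TR versus TD, 35 shared and 285 returning in TR, against 1019, 479, 994, 123 and 626. A pseudocount acts most on low genes, and a median of 151, 138 and 132 reads per gene leaves many low. The total counts of genes past 2-fold, shared and returning stayed within 1.5 times under quantile normalization, a filter of 5 TPM, FPKM, read counts over depth and GC centring. Dropping the filter could not change a count, since a gene under 1 TPM in every column cannot pass 2-fold with a pseudocount of 1. For TR versus TC the share of higher genes among those past 2-fold was 42.2%, 53.6% with quantile normalization and 65.8% with GC centring, and the cause was not tested. Lists beyond the central 95% numbered 4, 6 and 8 for TD versus TC, TR versus TC and TR versus TD, 6, 6 and 6 with a pseudocount of 0.1, 4, 6 and 7 with quantile normalization and 6, 6 and 8 with GC-matched lists. With zeros set to the floor of 3 reads, the keratinisation median for TD versus TC went from 0.96 to 0.20. The keratinisation list (TD versus TC) lay beyond the central 95% with a pseudocount of 0.1 and with GC-matched lists, the stem and dormancy list (TD versus TC) and the oxidative stress list (TR versus TD) with a pseudocount of 0.1, and the p53 list (TD versus TC) with GC-matched lists. Values of named genes past 2-fold moved by more than their counting error in 203 of 329 cases with GC centring, and of 331 cases in 68 with a pseudocount of 0.1, 64 with FPKM, 59 with read counts over depth and 33 with quantile normalization, with no change of direction in these.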

Other observations

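Of the tests in this part, those of the authors' scaling and of GC content on chromosome 16 were chosen after results were seen. Neighbouring S100 genes on chromosome 1 went different ways in TR against TC. S100A9, S100A8 and S100A7 (GRCh38, 153357854 to 153460701) were at least 2-fold higher in TR. Of the 5 listed S100 genes in the neighbouring stretch from 153534599 to 153616986, S100A6, S100A16 and S100A14 were at least 2-fold lower. S100A6 stood at 106.57 TPM in TC, 325.1 TPM in TD and 29.87 TPM in TR. The other genes of that stretch were low in TC and TR, with S100A4 at 3.02, 88.25 and 1.21 TPM and S100A2 at 0.35, 5.42 and 0.69 TPM. Genes outside the rule for naming, chosen after their values were seen, include the metallothioneins MT2A, at 3071 TPM in TC, 1376 TPM in TD and 7098 TPM in TR, and MT1X, at 392.2, 134.08 and 1177 TPM. The nuclear receptor PPARG was at 5.1, 19.32 and 1.58 TPM and the transcriptional repressor BCL6 at 14.36, 73.32 and 6.54 TPM.

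Other lists went as follows in TD against TC. Of 5 listed apoptosis regulators 2 were at least 2-fold higher and none was at least 2-fold lower, the BH3-only gene PMAIP1 at 2.22 TPM in TC and 22.48 TPM in TD and the death ligand TNFSF10 at 0.97 and 15.52 TPM. Of 6 hypoxia genes 4 were higher and 1 lower (percentile 95.5), with VEGFA at 16.71 and 49.65 TPM. Of 5 fatty acid synthesis genes 3 were higher (percentile 96.2), with the desaturase SCD at 340.26 and 779.93 TPM. Of 15 TGF-beta and BMP genes 4 were higher and 1 lower (percentile 83.3), with INHBA at 0.37 and 4.31 TPM. Basal markers (percentile 74.5), mesenchymal genes (50.5), drug metabolism and efflux (32.6), Notch, Wnt and Hedgehog (69.3) and inflammatory cytokines (24.6) lay within the central 95%, the NF-kB inhibitor NFKBIA being at 88.79 and 440.38 TPM. Lists with 2 to 4 listed members were luminal identity (3), lysosome and autophagy (2, both higher), unfolded protein response (2), amino acid metabolism (4), cholesterol synthesis (3), fatty acid oxidation (2), glycolysis (3), nuclear-encoded oxidative phosphorylation (2, both lower), DNA repair (4), chromatin regulators (4) and stroma markers (2, both lower). No mitochondrially encoded or ribosomal protein gene was listed.

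GC-rich genes were lower in the TD column, with a rank correlation of -0.364. Transcript length as the cause is argued against by a median correlation of -0.294 within 5 bins of length. The correlation was -0.351 on read counts, which decides nothing about the authors' length and depth scaling, since ratios were ordered nearly alike in TPM and in read counts (rank correlation 0.994 across 1046 genes). GC-dependent yield of the TD library stays open, as does the state of the cultures, which was not tested. In 419 genes listed for TR over TC alone the correlation was -0.037, past the bound of -0.05 set in advance against GC-dependent yield. Its bootstrap interval of -0.135 to 0.059 spans that bound. The rule requiring the interval to clear the bound was added after the correlation was seen. The whole interval lay above the separate, lower bound set in advance in favour of GC-dependent yield, so that prediction was not met. The selection limits these genes to under 2-fold in TD, so their correlation cannot decide the question.

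Genes on chromosome 16, the most extreme of 23 chromosomes in TD against TC and chosen after seeing that, were mostly lower in TD: 48 of 56 past 2-fold (85.7%, against 55.4% to 76.8% in the central 95% of GC-matched sets), 30 of 35 on the p side of the centromere and 18 of 21 on the q side. It was 1 of 3 chromosomes beyond that range, with chromosome 11 also lower (47 of 62) and chromosome 1 less often lower (43 of 106). GC-dependent yield is argued against as the whole cause, since chromosome 16 lay at percentile 98.99 of the most extreme of 23 chromosomes in 10000 shuffles of direction within GC bins, which take genes as independent and make no allowance for the 3 comparisons looked at. The metallothioneins MT2A, MT1F and MT1X, neighbours on chromosome 16 (56608199 to 56684196) and all lower in TD, were counted there as separate genes. A hypothesis is that the TD culture may carry fewer copies of chromosome 16. In 18 chromosome 16 genes listed for TR over TC alone the TD over TC median lay -0.221 from that of GC-matched sets, at percentile 4.82, short of the 2.5 set in advance, so copy number cannot be told apart from other causes at this number of genes.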
